A study of Homo sapiens with 16 samples.

How the data were processed

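The series holds RNA libraries of INA6 and JJN3 myeloma cells with CRISPR interference against KANSL2 or with a non-targeting guide, 3 libraries in each of 4 groups, and 4 JJN3 chromatin accessibility libraries that were not analysed here. Samples were grouped by their titles. Per the labels' protocols, poly(A) RNA was captured with oligo-dT beads and copied with random hexamers; whether the library kept strand is not given in the sources used here. Per the submitters' processing notes, Trim Galore, Bowtie2, HTSeq and DESeq2 were used with genome build hg38, without versions, settings or annotation; whether a splice-aware alignment was made is not given there. Genes that overlap on opposite strands and near-identical paralogs are therefore uncertain.

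The authors deposited 1 table of rlog values on the log2 scale for each line, with 28277 gene symbols and 6 libraries. The rlog transformation scales counts by size factors and shrinks each gene towards its mean, so it understates changes of genes with few reads. The 2 tables were normalised separately, so all tests were made within a table and no level was compared between lines. Depth per library is unknown, since the tables hold no counts, and no counting interval was computed. In INA6 8911 symbols and in JJN3 10073 symbols were at exactly 0 in all 6 libraries. Of the symbols, 27661 matched a current or older name in the reference tables. Coordinates come from the RefSeq annotation of GRCh38.p14, the same build as hg38. Some genes that every cell uses were at 0 or near the floor in both lines (EIF4A1 at 0; PSMB3 at −1.49 in INA6), chosen here after their values were seen, so a low value, also of a marker or MHC class II gene, does not show absence. No library pair was identical.

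Genes with a mean of at least 3 over the 6 libraries of a line were tested, 12511 in INA6 and 12282 in JJN3. limma 3.58.1 in R 4.3.3 was fitted per line (lmFit, then eBayes with a mean-variance trend), with no block, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. All p-values are two-sided. Adjusted p-values of genes within a line come from these limma fits, and differences are knockdown minus non-targeting on the log2 scale with n = 3 per arm. The standard errors of the named genes lay between 0.0376 and 0.107 in INA6 and between 0.0369 and 0.0825 in JJN3, and the adjusted p of those called was at most 0.0288 and 0.0127. Genes were tested for a difference between lines by the difference of the within-table differences over the root of their summed squared standard errors, with summed degrees of freedom and Benjamini-Hochberg adjustment over 11137 genes. With 3 against 3 libraries an exact permutation test of 1 gene cannot go below 0.1, so none was used.

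Before the data were examined, 35 gene lists were fixed: NSL complex, other MYST acetyltransferases, KANSL2 neighbours, plasma cell identity, B cell, T and NK cell, myeloid, stromal, MYC targets, G1/S replication, G2/M mitosis, p53 targets, BCL2 family members that promote death, survival genes, ER stress chaperones, ATF4 response, proteasome, oxidative phosphorylation, mitochondrial translation, mitochondrial genome, ribosomal proteins, interferon response, NF-kappaB targets, interleukin 6 and STAT3 targets, MHC class I, MHC class II, cholesterol synthesis, glycolysis and hypoxia, replication-dependent histones, DNA repair, immediate early, adhesion and migration, cereblon pathway, intraciliary transport, and lysosome and autophagy. Genes of the mitochondrial genome were not analysed here. Lists with at least 3 tested members, 32 per line, were tested with camera (preset inter-gene correlation 0.01) and adjusted over the lists. With an estimated correlation 0 lists passed in either line, 5 in INA6 and 7 in JJN3 having an unadjusted p below 0.05, and fry called 24 in each. camera tests a list against the other genes and fry against no change, so their p-values answer different questions, and the ranges given over a list's alternatives hold both. Counts of members are those called over all genes tested, beside those adjusted over the list alone.

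The genes named were chosen by a rule set before the data were examined: KANSL2, the NSL subunits, the 10 largest rises and falls per line (adjusted p below 0.05, mean of at least 5, no overlap between groups, no clone-based symbol), the 6 genes most raised and most lowered in both lines, up to 4 members of each list with the smallest p per line, and the 3 genes per direction with the smallest p for a difference between lines. Of the genes of this rule, 184 were called in INA6 and 192 in JJN3, and 95 and 98 of those are not printed, for length except 1 gene that is not reported here. Calls of these genes were checked under median centring, quantile normalisation, the replicate number as a block and leaving out each library. Under at least 1 of these, 12 and 14 of the unprinted calls were lost, as were 6 and 9 of the printed ones. For named genes the other alternatives were not counted. Alternatives were no filter, a minimum mean of 5, median centring, quantile normalisation, no variance trend, robust variances, replicate number as a block, a minimum absolute difference of 1, and leaving out each library. The removal of a smooth trend of the change with the mean value (lowess span 30%) and the camera test of list differences between lines (on the gene statistics) were chosen after the data were seen.

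The fits were tested on simulated data made from the real means and spreads. Noise was drawn independently for each gene, and 66 or 67 genes per line were shifted at each size. The real data hold many more changed genes, and genes that vary together, so the rates below may not carry over to them. Of genes shifted by 0.25, 77.6% were recovered in INA6 (12511 genes) and 92.5% in JJN3 (12282 genes). All genes shifted by 0.5 or 1 were recovered in both lines. False calls were 2.12% of calls in INA6 and 5.80% in JJN3. For the difference between lines (11137 genes) 61.5% were recovered at 0.25 and 100% at 0.5 and 1.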

Results

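Messenger RNA was profiled in 2 established human multiple myeloma cell lines, INA6 and JJN3, in which KANSL2 was repressed by CRISPR interference, where a catalytically inactive Cas9 fused to a repressor domain is brought to a gene by a guide RNA. INA6 is a plasma cell line known to depend on interleukin 6 for growth, and JJN3 grows without it. KANSL2 is a subunit of the NSL complex, which holds the histone H4 acetyltransferase KAT8. Each line had 3 knockdown libraries and 3 libraries with a non-targeting guide, 12 RNA libraries in all. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The values were regularised log (rlog) expression values on the log2 scale, normalised in each line separately, and the depth of the libraries is unknown. Scaling by size factors makes rises and falls relative to the other genes of a library. A change in total RNA per cell would not be seen. Another 4 JJN3 libraries for chromatin accessibility (2 control, 2 knockdown) were not analysed here. The comparisons ask which genes and pathways change when KANSL2 is repressed in each line, and whether the 2 lines change alike.

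The target gene was lower in the knockdown arm of both lines, and by more in JJN3. KANSL2 lies on chromosome 12 from 48653211 to 48682238 in the GRCh38.p14 RefSeq annotation. In INA6 its rlog value was 8.08 ± 0.0757 (SD, n = 3) in the controls and 7.69 ± 0.0809 (SD, n = 3) in the knockdown libraries. The difference of −0.39 (SE 0.0625) leaves 76.4% of the control level, with a limma adjusted p = 3.06e-05. In JJN3 the value fell from 7.23 ± 0.0317 to 6.01 ± 0.0435 (SD, n = 3 each), a difference of −1.21 (SE 0.0559) that leaves 43.1% of the control level, with adjusted p = 1.48e-16. Every knockdown library lay below every control library of its line. KANSL2 had the fall of rank 2 among 12282 tested genes in JJN3 and of rank 555 among 12511 in INA6. The difference between the 2 changes was 0.82 (adjusted p = 2.11e-11).

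**Figure D1:**
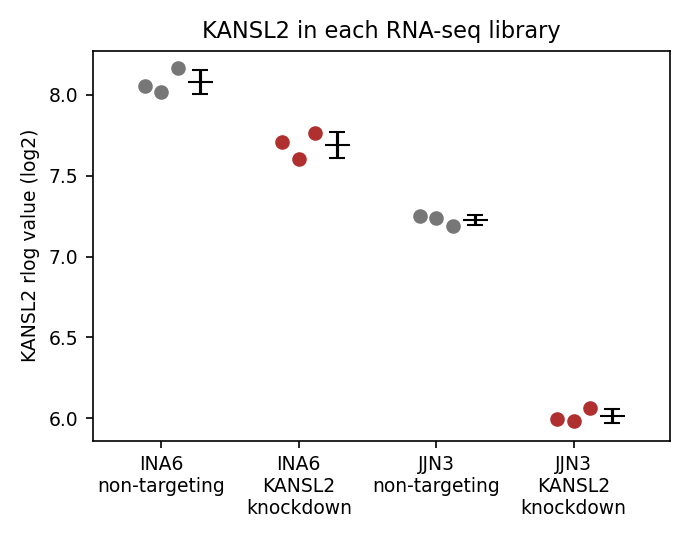
KANSL2 rlog value (log2 scale) in each RNA library of INA6 and JJN3. Points are single libraries, 3 per group, and the black marks are group means with SD; the knockdown means were 7.69 in INA6 and 6.01 in JJN3, and the levels of the lines come from separately normalised tables.

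The other subunits of the NSL complex did not move together. In INA6, 3 of 7 tested subunits rose, HCFC1 (0.41), MCRS1 (0.31) and WDR5 (0.17), and 3 fell, PHF20 (−0.25), KANSL3 (−0.24) and OGT (−0.12); the list test gave adjusted p = 0.846 with a median of 0.02. In JJN3, WDR5 (0.24), HCFC1 (0.18) and OGT (0.18) rose and KAT8, the catalytic subunit, fell (−0.18), with a median of 0.04 and a list adjusted p = 0.449. KAT8 was at 0.02 in INA6 (adjusted p = 0.817). Several of these calls were fragile. In INA6, WDR5 was lost with quantile normalisation (adjusted p = 0.081) and without control replicate 2 (0.16, adjusted p = 0.0597), control replicate 3 (0.13, 0.0894) or knockdown replicate 2 (0.15, 0.0751), the range over the alternatives being 0.00104 to 0.0894. OGT in INA6 was lost with median centring (0.104) and without control replicate 1 (−0.10, 0.0903), control replicate 2 (−0.12, 0.0518) or knockdown replicate 2 (−0.11, 0.0777), and was at −0.21 with quantile normalisation, in a range of 0.000256 to 0.104. In JJN3, KAT8 was lost without control replicate 2 (−0.14, adjusted p = 0.0695) and with quantile normalisation (0.0647; range 0.00738 to 0.0695). Quantile normalisation also ended the JJN3 calls of HCFC1 (0.08, adjusted p = 0.0553; range 3.07e-05 to 0.0553) and OGT (0.08, adjusted p = 0.0923; range 0.000151 to 0.0923).

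KANSL1 had a mean rlog value of 1.15 in INA6 and 0.742 in JJN3, below the minimum of 3, and was not tested, though a low value in these tables does not show that a gene is not expressed. Of the protein-coding neighbours of KANSL2 on chromosome 12, CCNT1 (48688458 to 48716707), the closest gene on the list, was higher by 0.44 in INA6 and 0.23 in JJN3. The helicase gene DDX23 was higher by 0.21 and 0.29. The calcium channel subunit gene CACNB3 was lower by −0.36 in INA6 and −0.19 in JJN3, where the call was lost with quantile normalisation (adjusted p = 0.0606) and without knockdown replicate 1 (−0.12, adjusted p = 0.095), the range being 0.00474 to 0.095. The neighbours as a list did not pass the test, with a median of 0.12 in INA6 (4 up and 1 down of 7, adjusted p = 0.25) and 0.10 in JJN3 (4 up and 2 down of 8, adjusted p = 0.343). The other MYST family acetyltransferases and their partners did not pass either (INA6 8 up and 2 down of 20, median 0.08, adjusted p = 0.0934; JJN3 7 up and 3 down of 20, median 0.07, adjusted p = 0.449), though ING4, a reader of methylated histone H3, fell in both lines (−0.41 and −0.55).

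In INA6, genes of interleukin 6 signalling and of the immediate early response were among those that fell most, and CCL2 and PECAM1 among those that rose most. SOCS3, which restrains interleukin 6 signalling and is induced by it, fell by 2.26 on the log2 scale (SE 0.0545). The transcription factors EGR1 (−1.90), FOS (−1.49) and KLF2 (−1.35) and the activation marker CD69 (−1.58) fell, as did DEPP1 (−1.32), the antiproliferative gene BTG2 (−1.22), the glycolytic regulator PFKFB4 (−1.22), the aldolase gene ALDOC (−1.19) and TEX19 (−1.17). The chemokine CCL2 rose by 2.02 (SE 0.107), PECAM1, an adhesion receptor, by 1.22, the stress-responsive transcription factor ATF5 by 1.04, RELN by 1.02, the interferon-induced gene MX1 by 0.97, the DNA methylation factor UHRF1 by 0.87 and the nucleotide receptor P2RY6 by 0.86. The rule that picked these genes required that the 3 knockdown and 3 control values did not overlap. In total 3084 genes were higher and 3000 lower (limma, adjusted p below 0.05), 48.6% of the 12511 tested. Most changes were small: the median absolute difference of the called genes was 0.24, and 23 called genes (4 up, 19 down) reached 1. When each library was centred on its median, 3904 genes were higher and 2400 lower. The 2 groups did not overlap for 55.2% of the genes. Chance gives 10% only if the 6 libraries are exchangeable, which is unknown because the replicates of an arm may share a culture.

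Growth-related lists, MYC targets among them, rose in INA6, while MYC itself fell. Of 29 tested MYC targets 28 rose and 0 fell (median 0.40, list adjusted p = 5.35e-14), including the ribosome biogenesis genes PPAN (0.72) and MRTO4 (0.56), the transferrin receptor TFRC (0.63) and the mitochondrial chaperone HSPD1 (0.56); adjusted p = 0.26 with an estimated correlation. Of 33 replication and G1/S genes 32 rose and 0 fell (median 0.29, adjusted p = 5.35e-14), with the replicative helicase subunits MCM5 at 0.63 and MCM4 at 0.56; adjusted p = 0.177 with an estimated correlation. Of 29 proteasome subunits 26 rose and 0 fell (median 0.28, adjusted p = 4.36e-10), among them PSMD2 (0.47) and PSMD11 (0.47); adjusted p = 0.266 with an estimated correlation. Mitochondrial genes moved the same way. Of 33 mitochondrial translation genes 26 rose and 0 fell (median 0.19, adjusted p = 5.94e-07), including MRPL20 (0.50) and MRPS12 (0.42); adjusted p = 0.266 with an estimated correlation. Of 41 nuclear genes of oxidative phosphorylation 25 rose and 1 fell (median 0.18, adjusted p = 5.25e-06), including NDUFS7 (0.51) and the ATP synthase gene ATP5F1B (0.35); adjusted p = 0.362 with an estimated correlation. Of 33 mitosis genes 17 rose and 2 fell (median 0.12, adjusted p = 0.000328), with CDC20 at 0.40 and the kinase PLK1 at 0.39; adjusted p = 0.362 with an estimated correlation.

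Ribosomal protein, cereblon pathway and DNA repair lists also rose in INA6. Of 52 ribosomal protein genes 24 rose and 5 fell (median 0.12, adjusted p = 0.00732), RPL23 by 0.47, with adjusted p = 0.541 with an estimated correlation. That call was lost with quantile normalisation (adjusted p = 0.0837) and after a trend of the change with expression level was removed (0.144), in a range over the alternatives of 0.00083 to 0.541. Of 12 genes of the cereblon ligase pathway, the target of immunomodulatory drugs, 8 rose and 0 fell (median 0.20, adjusted p = 0.0182), including UBE2G1 (0.36), with adjusted p = 0.362 with an estimated correlation. It was lost with quantile normalisation (0.098) and with the trend removed (0.117), the range being 0.00645 to 0.362. Of 28 DNA repair genes 10 rose and 1 fell (median 0.09, adjusted p = 0.0182), XRCC2 by 0.54, with adjusted p = 0.362 with an estimated correlation. Without knockdown replicate 1 the median was 0.07 and the adjusted p 0.0584, the range being 0.00463 to 0.362.

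Lists of immediate early, interleukin 6, plasma cell, glycolytic, histone and ciliary genes fell in INA6. Of 17 immediate early and heat shock genes, which also respond to handling of cells, 12 fell and 1 rose (median −0.77, adjusted p = 1.1e-08), with JUNB at −0.98 and ZFP36 at −0.96; adjusted p = 0.26 with an estimated correlation. Of 18 targets of interleukin 6 and STAT3, which share FOS and JUNB with that list, 11 fell and 1 rose (median −0.22, adjusted p = 0.000128), with the kinase PIM1 at −0.46 and MYC at −0.52; adjusted p = 0.266 with an estimated correlation. Of 22 plasma cell identity genes 13 fell and 6 rose (median −0.26, adjusted p = 0.000563). Those that fell included the immunoglobulin joining chain JCHAIN (−0.89), the plasma cell regulator PRDM1 (−0.72) and the therapeutic targets SLAMF7 (−0.71) and TNFRSF17, which encodes BCMA (−0.56), while IRF4 rose by 0.29; adjusted p = 0.362 with an estimated correlation. Of 29 glycolysis and hypoxia genes 13 fell and 6 rose (median −0.13, adjusted p = 0.00207), including P4HA1 (−1.11), BNIP3L (−1.02) and VEGFA (−0.40); adjusted p = 0.362 with an estimated correlation. Of 26 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail and so also read library preparation, 12 fell and 1 rose (median −0.14, adjusted p = 0.00355), with H1-2 at −0.49 and H2BC21 at −0.44; adjusted p = 0.26 with an estimated correlation. Their median was −0.08 with quantile normalisation. Of 25 intraciliary transport genes 12 fell and 1 rose (median −0.13, adjusted p = 0.0126), among them BBS2 (−0.38) and BBS1 (−0.34); adjusted p = 0.26 with an estimated correlation. KIF3B was at −0.19 (adjusted p = 0.0131) and lost its call without control replicate 3 (−0.11, adjusted p = 0.135; range 0.00324 to 0.135). The list's call was lost with quantile normalisation (0.0837) and with the expression trend removed (0.107), the range being 0.00175 to 0.26.

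The other lists tested in INA6 did not pass the camera test. Interferon-stimulated genes had 11 up and 2 down of 26 (median 0.02, adjusted p = 0.0739), p53 targets 4 up and 10 down of 23 (−0.10, 0.161), and MHC class I genes 1 up and 5 down of 10 (−0.12, 0.163). Adhesion and migration genes had 3 up and 7 down of 16 (−0.08, 0.244), death-promoting BCL2 family members 5 up and 2 down of 9 (0.15, 0.244), and survival genes 3 up and 3 down of 10 (−0.03, 0.778). The interferon list passed without control replicate 3 (adjusted p = 0.0261), without knockdown replicate 3 (0.018) and with fry (0.0433), which tests against no change and not against the other genes, in a range over the alternatives of 0.018 to 0.477. ER stress genes had 8 up and 7 down of 27 (−0.01, 0.747), ATF4 response genes 6 up and 3 down of 23 (0.05, 0.594), and lysosome and autophagy genes 9 up and 6 down of 27 (0.01, 0.752). NF-kappaB targets had 7 up and 3 down of 17 (adjusted p = 0.48), where the median of −0.01 and the mean of 0.11 differ in sign. Cholesterol synthesis genes had 6 up and 4 down of 24 (adjusted p = 0.95), where the median of 0.002 and the mean of −0.02 differ in sign. Of the markers of other cells that reached the minimum mean, B cell genes had 0 up and 1 down of 10 (0.002, 0.937), T and NK cell genes 0 up and 1 down of 4 (−0.06, 0.347), and stromal genes 0 up and 0 down of 3 (0.04, 0.828). With fry, 9 lists that camera did not call passed. With the expression trend removed the ER stress list passed (adjusted p = 0.0449, downwards; range 0.0434 to 0.819). Only 2 myeloid and 2 MHC class II genes were tested, too few for the list test, and none of them was called. Adjusted over the list alone, 18 mitosis genes, 27 proteasome genes and 28 oxidative phosphorylation genes rose, 6 ribosomal protein, 14 glycolysis and 13 histone genes fell, and 1 myeloid gene rose and 1 fell. The counts of the other lists were equal when adjusted over the list alone.

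In JJN3, DLL4 and ATF3 were the named genes that rose most, and MYOC and KANSL2 those that fell most. The Notch ligand DLL4 rose by 1.15 (SE 0.0631), the stress-induced transcription factor ATF3 by 1.13, the receptor EPHB2 by 0.92, the germinal centre repressor BCL6 by 0.92, FOSB by 0.88, the replication licensing factor CDC6 by 0.80, HES6 by 0.79, the kinase PIM1 by 0.78 and the somatostatin receptor SSTR2 by 0.78. Besides KANSL2, MYOC fell by 1.25 (SE 0.0623), TXNIP, which inhibits thioredoxin and glucose uptake, by 1.15, the transporter SLCO2B1 by 1.15, the complement protease C1R by 1.15, ZNF358 by 1.00, the kinase MAP3K10 by 1.00, HES7 by 0.86 and TMEM254 by 0.85. That the groups did not overlap in these genes was again required by the rule that picked them. In total 3135 genes were higher and 3129 lower (limma, adjusted p below 0.05), 51.0% of the 12282 tested. When each library was centred on its median, 3768 genes were higher and 2571 lower. The median absolute difference of the called genes was 0.21, and 7 called genes (2 up, 5 down) reached 1. The groups did not overlap for 56.1% of the genes, where chance gives 10% only if the 6 libraries are exchangeable, which is again unknown.

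Lists of MYC targets, replication, proteasome and secretory pathway genes rose in JJN3, while MYC itself fell. Of 29 MYC targets 26 rose and 1 fell (median 0.33, adjusted p = 7.04e-12), PPAN by 0.52, BOP1 by 0.46 and NOP56 by 0.44; adjusted p = 0.0904 with an estimated correlation. Of 33 replication and G1/S genes 29 rose and 0 fell (median 0.32, adjusted p = 4.7e-13), with MCM4 at 0.56, MCM2 at 0.49 and the flap endonuclease FEN1 at 0.49; adjusted p = 0.0904 with an estimated correlation. Of 29 proteasome subunits 25 rose and 0 fell (median 0.22, adjusted p = 5.45e-09), with PSMD2 at 0.47, PSMD12 at 0.44 and PSMC4 at 0.40; adjusted p = 0.141 with an estimated correlation. Of 26 endoplasmic reticulum stress and chaperone genes 16 rose and 0 fell (median 0.17, adjusted p = 2.7e-05), among them the translocon subunit SEC61A1 (0.42), CALR (0.42) and HYOU1 (0.36); adjusted p = 0.0904 with an estimated correlation. Their median was 0.11 with quantile normalisation and 0.10 with the expression trend removed. Of 23 ATF4 response genes 14 rose and 3 fell (median 0.14, adjusted p = 0.0017), with the amino acid transporter subunit SLC3A2 at 0.53, while DDIT4 fell by 0.85; adjusted p = 0.141 with an estimated correlation. Of 6 MHC class II genes 5 rose and 0 fell (median 0.24, adjusted p = 0.00134), with the class II transactivator CIITA at 0.61 and HLA-DQB1 at 0.37; adjusted p = 0.17 with an estimated correlation.

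Plasma cell and histone lists also rose in JJN3. Of 22 plasma cell identity genes 14 rose and 3 fell (median 0.18, adjusted p = 0.00473), including TNFRSF17 (0.58), IRF4 (0.45), the coactivator POU2AF1 (0.40) and PRDM1 (0.28, and 0.18 with quantile normalisation); adjusted p = 0.205 with an estimated correlation. Of 19 replication-dependent histone genes 11 rose and 1 fell (median 0.23, adjusted p = 0.000738), with H2BC4 at 0.52 and H2BC12 at 0.51; adjusted p = 0.205 with an estimated correlation. Of 20 interleukin 6 and STAT3 targets 11 rose and 6 fell (median 0.18, adjusted p = 0.0254), with SOCS1 at 0.77 and SOCS3 at 0.50, while MYC fell by 0.40; adjusted p = 0.319 with an estimated correlation. That call was lost with quantile normalisation (0.0812) and with the expression trend removed (0.0548), where the median was 0.10, the range over the alternatives being 0.00273 to 0.319. Of 52 ribosomal protein genes 20 rose and 3 fell (median 0.07, adjusted p = 0.0275), RPL23 by 0.39; adjusted p = 0.529 with an estimated correlation. It was lost with quantile normalisation (0.65), a minimum mean of 5 (0.0731), the trend removed (0.642), without control replicate 1 (median 0.07, 0.0812) and without knockdown replicate 3 (median 0.06, 0.111), the range being 0.0111 to 0.65. Of 24 cholesterol synthesis genes 11 rose and 3 fell (median 0.09, adjusted p = 0.0249); adjusted p = 0.437 with an estimated correlation. It was lost with quantile normalisation (0.174), the trend removed (0.222) and without control replicate 3 (median 0.08, adjusted p = 0.0503), the range being 0.0083 to 0.437.

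The immediate early list was past the threshold in JJN3 with members going both ways. Of 16 tested genes 8 rose and 4 fell (median 0.12, adjusted p = 0.0398), with KLF2 at 0.65 and FOS at 0.63 upwards and ZFP36 at −0.51; adjusted p = 0.529 with an estimated correlation. The call was lost with fry (0.0674), quantile normalisation (0.313), median centring (0.0552), a minimum mean of 5 (0.127) and the trend removed (0.222). It was also lost without control replicate 3 (median 0.05, 0.164) and without knockdown replicate 3 (median 0.16, 0.0683), while without control replicate 1 the median was 0.23 (0.000743); the range over the alternatives was 0.000743 to 0.529. Another split of the 6 libraries gave an absolute median of 0.143, above the 0.121 of the real grouping.

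Glycolytic and ciliary genes fell in JJN3. Of 30 glycolysis and hypoxia genes 18 fell and 4 rose (median −0.13, adjusted p = 0.000637), with PFKFB4 at −0.73 and VEGFA at −0.44; adjusted p = 0.0958 with an estimated correlation. Their median was −0.21 with the expression trend removed. Of 25 intraciliary transport genes 16 fell and 0 rose (median −0.17, adjusted p = 0.000267), with BBS4 at −0.43, the kinesin KIF3B at −0.35 and BBS1 at −0.30; adjusted p = 0.205 with an estimated correlation. Their median was −0.10 with quantile normalisation.

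The other lists tested in JJN3 did not pass the camera test. B cell genes had 5 up and 2 down of 9 (median 0.20, adjusted p = 0.0661), DNA repair genes 11 up and 3 down of 28 (0.09, 0.0661), and mitosis genes 2 up and 10 down of 33 (−0.08, 0.0729), with NEK2 at −0.44 and TOP2A at −0.26 among those that fell. These 3 lists passed with fry, quantile normalisation and the expression trend removed, where the adjusted p was 0.0355, 0.0286 and 0.0365, in ranges over the alternatives of 0.0078 to 0.471, 0.00187 to 0.216 and 0.025 to 0.529. The B cell list also passed with a minimum mean of 5 (0.0413) and without control replicate 1 (0.0258), knockdown replicate 1 (0.0375) or knockdown replicate 2 (0.0402), DNA repair without knockdown replicate 2 (0.046) and mitosis without knockdown replicate 1 (0.025). Mitochondrial translation genes had 12 up and 6 down of 33 (0.05, 0.161), oxidative phosphorylation genes 9 up and 5 down of 41 (0.04, 0.388), and cereblon pathway genes 4 up and 2 down of 12 (0.06, 0.161). Interferon-stimulated genes had 4 up and 10 down of 23 (−0.02, 0.227), adhesion and migration genes 9 up and 5 down of 18 (0.09, 0.266), and MHC class I genes 1 up and 3 down of 10 (−0.07, 0.388). NF-kappaB targets had 6 up and 3 down of 14 (0.08, 0.449), stromal genes 0 up and 2 down of 4 (−0.06, 0.449), and lysosome and autophagy genes 6 up and 4 down of 27 (0.01, 0.694). The p53 targets had 9 up and 7 down of 23 (0.05, 0.73) and death-promoting BCL2 family members 3 up and 3 down of 10 (−0.005, 0.879). Survival genes had 3 up and 4 down of 9 (adjusted p = 0.864), where the median of −0.03 and the mean of 0.01 differ in sign. In JJN3 fry passed 11 lists that camera did not call. The 2 tested myeloid genes were not called, and the 1 tested T and NK cell gene was lower. Adjusted over the list alone, 8 oxidative phosphorylation genes rose and 4 fell, 13 mitochondrial translation, 5 interferon, 7 NF-kappaB and 6 MHC class II genes rose, and 4 cholesterol and 6 adhesion genes fell. The counts of the other lists were equal when adjusted over the list alone. Lists also pass this test when libraries are regrouped: other splits of the 6 libraries called up to 14 lists in INA6 and up to 11 in JJN3, against 15 and 14 in the real grouping.

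**Figure D2:**
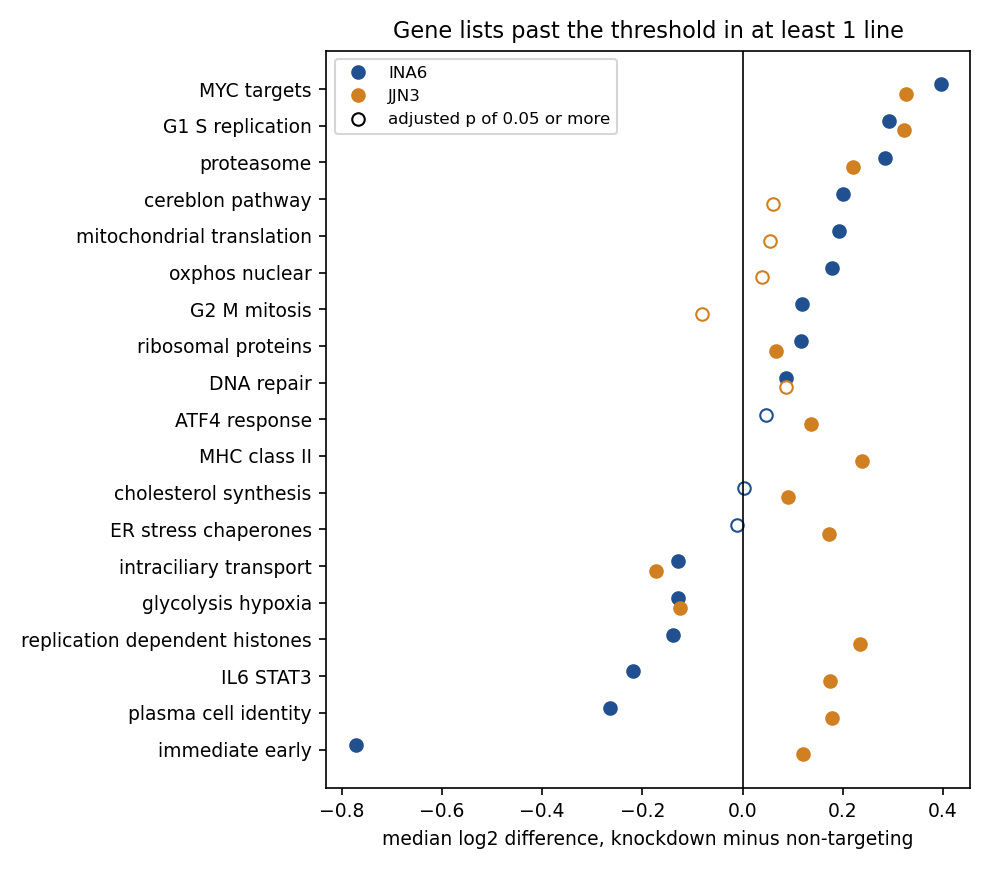
Median log2 difference (knockdown minus non-targeting, x axis) of the genes of each list past the threshold in at least 1 line. Blue points are INA6, orange points JJN3 and open points lists with a preset-correlation adjusted p of 0.05 or more; MYC targets lie at 0.40 and 0.33, and immediate early genes at −0.77 in INA6 and 0.12 in JJN3.

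The changes of the 2 lines overlapped more than independent lists would. Among 11137 genes tested in both, 1577 were higher in both, against 762 from independent lists (odds ratio 6.08), and 1372 were lower in both, against 670 (odds ratio 5.24). Of the 3384 genes called in both lines, 87.1% changed in the same direction and 435 went opposite ways. Across these 11137 genes, which are not independent replicates, the differences of the lines had a Pearson r of 0.49 and a Spearman rho of 0.52. In each line the change also rose with expression level (Spearman rho 0.196 in INA6 and 0.269 in JJN3). A trend common to both lines would add to the overlap and the correlation, and neither was computed with the trend removed. The genes with the strongest rise in both were ATF5 (1.04 in INA6, 0.70 in JJN3), the vasopressin receptor AVPR2 (0.74, 0.62), KLHL21 (0.84, 0.58) and MIR17HG, the host transcript of a microRNA cluster (0.75, 0.58). Those with the strongest fall in both included TMEM8B (−0.91, −0.76), ZSWIM4 (−0.74, −0.80), PFKFB4 (−1.22, −0.73), TXNIP (−0.71, −1.15), MAP3K10 (−0.70, −0.997) and VAMP4 (−0.62, −0.65). The lists of MYC targets, G1/S genes and proteasome subunits, which rose in both lines, did not pass a test of a difference between them (adjusted p = 0.115, 0.999 and 0.609).

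The change itself differed between INA6 and JJN3 for 3342 genes, 30.0% of those tested in both, with 1733 higher and 1609 lower in INA6 (difference of the within-line differences, adjusted p below 0.05). SOCS3 fell by 2.26 in INA6 and rose by 0.50 in JJN3, FOS changed by −1.49 and 0.63, KLF2 by −1.35 and 0.65, PIM1 by −0.46 and 0.78, and TNFRSF17 by −0.56 and 0.58. In the other direction, ZNF358 and C1R, which fell in JJN3, differed by 0.94 and 1.01, and TNFAIP3, an inhibitor of NF-kappaB signalling, was at 0.42 in INA6 and −0.51 in JJN3. As lists, immediate early genes (median difference −0.85, adjusted p = 2.01e-22), interleukin 6 and STAT3 targets (−0.41, 5.08e-12), plasma cell genes (−0.27, 1.21e-10), replication-dependent histones (−0.43, 5.42e-10) and ER stress genes (−0.20, 9.18e-07) were lower in INA6 relative to JJN3. Mitosis (0.22, 4.01e-07), oxidative phosphorylation (0.15, 0.000358) and mitochondrial translation genes (0.12, 0.000495) were higher. In all, 13 of 31 lists differed with this test, a preset-correlation test of the gene statistics chosen after the data were seen. As many lists differed in 2 of 81 joint splits that regroup the libraries of both lines, and in 15 of 18 that keep the real grouping of 1 line.

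**Figure D3:**
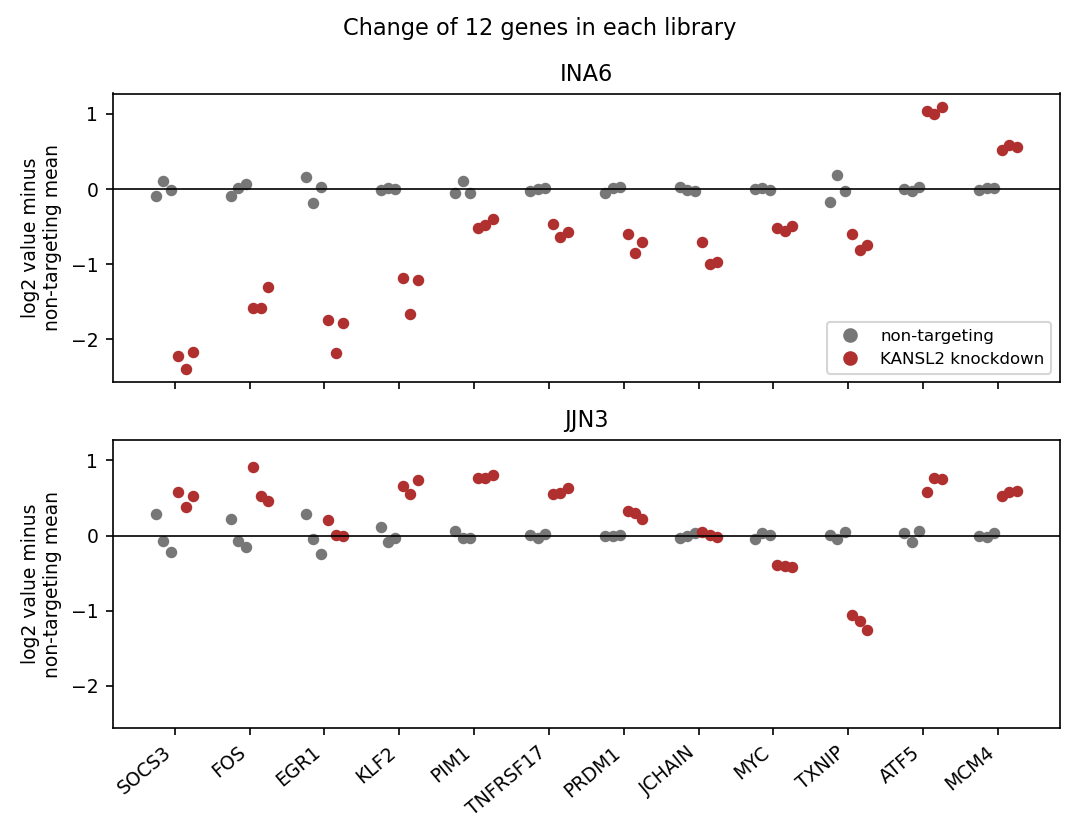
Log2 rlog value of 12 genes in each library minus the mean of the 3 non-targeting libraries of the same line (y axis), INA6 above and JJN3 below. Grey points are non-targeting and red points knockdown libraries; SOCS3, FOS, KLF2, PIM1 and TNFRSF17 lie below 0 in the INA6 and above 0 in the JJN3 knockdown libraries, while MYC and TXNIP lie below 0 and ATF5 and MCM4 above 0 in both lines.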

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

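Of the tests below, the list test between lines, the removal of the expression trend, the tests for an exchanged library and for cells without repression, and the count over all 100 joint splits were chosen after the results they bear on were seen. Of 98 named genes tested in both lines, the change of 69 differed between INA6 and JJN3 (adjusted p below 0.05), as did the change of 13 of 31 lists. Over all genes tested in both lines the share of genes was 30.0%. Named genes were picked partly for large changes or small p-values in these data, which favours a larger share. Values are the INA6 change minus the JJN3 change on the log2 scale.

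Genes lower in INA6 relative to JJN3 are grouped here by hand, and the groups are not in order of size. Signalling and early response genes were SOCS3 (−2.76), FOS (−2.12), KLF2 (−2.00), EGR1 (−1.97), CD69 (−1.41), PIM1 (−1.24) and ATF3 (−1.15). Also in this group were BCL6 (−0.91), FOSB (−0.88), JUNB (−0.81), BTG2 (−0.66), SOCS1 (−0.63) and ZFP36 (−0.46). Plasma cell genes were TNFRSF17 (−1.14), PRDM1 (−0.998), SLAMF7 (−0.91), JCHAIN (−0.91), POU2AF1 (−0.73) and IRF4 (−0.16). Histone genes were H1-2 (−0.88), H2BC12 (−0.70), H2BC4 (−0.62) and H2BC21 (−0.60). Metabolic and secretory genes were ALDOC (−1.08), P4HA1 (−0.91), BNIP3L (−0.69), SLC3A2 (−0.59), PFKFB4 (−0.49), SEC61A1 (−0.31), HYOU1 (−0.25) and CALR (−0.20). The others were TEX19 (−1.11), DLL4 (−1.10), DEPP1 (−0.99), SSTR2 (−0.73), HES6 (−0.58), CIITA (−0.53), CDC6 (−0.40), FEN1 (−0.32), OGT (−0.29), PHF20 (−0.21) and KANSL3 (−0.16).

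Genes higher in INA6 relative to JJN3 were C1R (1.01), ZNF358 (0.94), TNFAIP3 (0.93), KANSL2 (0.82), HES7 (0.65), PLK1 (0.60), NDUFS7 (0.48), CDC20 (0.48), TXNIP (0.43), TMEM254 (0.40), XRCC2 (0.35), ATF5 (0.34), DDIT4 (0.33), UHRF1 (0.33), P2RY6 (0.31), MAP3K10 (0.30), HSPD1 (0.29), TOP2A (0.28), MCRS1 (0.26), TFRC (0.26), KLHL21 (0.26), PSMD11 (0.25), NEK2 (0.25), HCFC1 (0.22), CCNT1 (0.21), ATP5F1B (0.21) and PPAN (0.20).

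The median differences of the lists that differed were −0.85 for immediate early genes, −0.43 for replication-dependent histones, −0.41 for interleukin 6 and STAT3 targets, −0.27 for plasma cell genes, −0.20 for ER stress genes, −0.18 for p53 targets, −0.0949 for cholesterol synthesis, −0.0838 for adhesion and migration and −0.0413 for the ATF4 response. They were 0.22 for mitosis, 0.15 for oxidative phosphorylation, 0.15 for interferon-stimulated genes and 0.12 for mitochondrial translation. The 10 splits of each line give 100 joint splits. Before they were run, the 18 that keep the real grouping of 1 line were left out because they hold that line's response, and the count over all 100 was added later. With the real grouping counted, as many lists differed in 18 of the 100 splits (real 13, highest other 16). Of these, 15 keep 1 line real and so hold its response, and 2 are among the 81 that regroup both lines (highest 15). The share is above 0.05 with the first kind of split and below it without, so no verdict on chance is drawn for the number of differing lists. As many single genes differed in 2 of the 100 (real 3342, highest other 3366), and as many genes were called in the same direction in 1 of the 100 (real 2949, highest other 0). Neither count decides whether chance is excluded: a regrouped line called 0 genes with limma (up to 317 at an unadjusted p below 0.05), which fixes the overlap at 0, and the splits that keep 1 line real hold that line's own response, with 2024 to 3366 genes.

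KANSL2 fell less in INA6 than in JJN3, and 3 technical explanations were tested. An exchanged library is argued against, because the highest INA6 knockdown value lay 0.26 under the lowest control, a gap of −0.26. Shrinkage by the rlog transformation stays open. Changes of genes of a similar mean were not smaller in INA6 as a set, with 1.16 times the SD in JJN3. That SD mixes shrinkage with the size of each line's response, so it cannot separate them. Fewer repressed INA6 cells also stay open. With an equal response per repressed cell, changes in INA6 would be smaller, roughly by the ratio of the log2 differences of KANSL2, 0.320. Among 5742 genes called in JJN3 the ratio had a median of 0.610 and a lower quartile of 0.103, on either side of it. A mixture of cells scales linear levels and not log2 values, and a ratio from linear levels was not computed. A bound set earlier, on the lower quartile in 2948 genes called in the same direction in both lines (0.794), was wrong, because picking genes by their INA6 call removes small ratios. A weaker repression in each INA6 cell may also remain, and was not tested.

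The immediate early list fell in INA6. A single library is argued against: the weakest median with 1 library left out was −0.61. Handling of the cells, to which these genes also respond, cannot be told apart from the knockdown, because each arm holds all libraries of its kind: the highest knockdown mean over the list lay under the lowest control mean, a difference of −0.55. Both handling and a response to lower KANSL2 may account for the fall. The same limit holds for the fall of interleukin 6 and STAT3 targets in INA6, SOCS3 included. The library means over that list were 9.35 to 9.45 in the knockdown arm and 9.80 to 9.81 in the control arm.

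MYC target, G1/S and proteasome lists rose in both lines. MYC itself fell in both, by −0.54 to −0.49 in INA6 and −0.43 to −0.38 in JJN3 over the alternatives. MYC activity was not measured. After a smooth trend of the change with expression level was removed, the smallest ratio of a list's median to its value before was 0.814, and after a trend with gene length 0.946, with all 6 list tests past the threshold each time, so both trends are argued against as the whole cause. A response to lower KANSL2 may underlie the rise, as a hypothesis. A difference in handling of the arms cannot be told apart from it, because each arm holds all libraries of its kind. With an estimated correlation the camera adjusted p of each list is above 0.05. Other splits of the libraries gave smaller absolute medians for each of these lists in both lines. Each such split exchanges 1 library between the arms, which by itself shrinks an arm difference. The smaller medians are therefore no support for the rise. In INA6 the largest were 0.17 for MYC targets, 0.15 for G1/S genes and 0.13 for proteasome subunits, against 0.40, 0.29 and 0.28. In JJN3 they were 0.12, 0.14 and 0.12, against 0.33, 0.32 and 0.22. For immediate early genes in JJN3 another split reached 0.143, above the real 0.121.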

How the results depend on the processing

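The removal of the expression trend was chosen after the data were seen. No named gene or list that was called reversed under the alternatives run for it. Reversals were not counted for the other called genes or for the gene families. Among the named genes and called lists, 2097 values under alternatives stayed on their side of the threshold, 90 lost the call and 8 gained one. Of the 2097, 23 values of 10 results that were not called changed sign.

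A minimum absolute difference of 1 left 23 genes in INA6 and 7 in JJN3. With camera's estimated correlation 0 lists passed in either line (5 and 7 at an unadjusted p below 0.05), and with fry 24 in each. The correlation between lines was 0.51 with a minimum mean of 5, 0.46 without a filter and 0.47 with quantile normalisation. With 1 library left out, 5034 to 6093 genes were called in INA6 and 5332 to 6078 in JJN3, KANSL2 was at −0.42 to −0.34 and −1.24 to −1.20, and 14 to 16 and 12 to 16 lists passed. The overlap was 2598 to 2942 genes, the correlation 0.48 to 0.49 and the number of genes differing between lines 2723 to 3434. The cause of these shifts was not tested.

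The values showed no sign that replicate numbers pair the samples, though 3 libraries per arm cannot show that no pairing existed. The mean of each arm was subtracted from every gene before libraries were correlated. Same-numbered knockdown and control libraries then had correlations of −0.18, −0.07 and −0.30 in INA6 and 0.005, −0.01 and 0.002 in JJN3. No knockdown library had its highest such correlation with the control library of its own number. With the replicate block 5626 genes were called in INA6 and 6205 in JJN3, 16 and 14 lists passed, the list gained in INA6 being interferon-stimulated genes (adjusted p = 0.0364; range over the alternatives 0.018 to 0.477), 2787 genes overlapped, the correlation was 0.49 and 2976 genes differed between lines.

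Beyond the calls named with the results, 3 INA6 calls were lost with quantile normalisation and without single libraries. These were SEC61A1 (without control replicate 1, 0.09, control replicate 3, 0.10, or knockdown replicate 3, 0.09), HYOU1 (0.04 with quantile normalisation; without control replicate 1, 0.09, control replicate 2, 0.12, or knockdown replicate 3, 0.08) and HES6 (without control replicate 3, 0.16, or knockdown replicate 3, 0.13). Their adjusted p ranged over the alternatives from 0.00364 to 0.11, 0.00423 to 0.338 and 0.00231 to 0.066. In JJN3, CD69 was lost without control replicate 1 (−0.10) or knockdown replicate 3 (−0.14) and with quantile normalisation, JUNB without control replicate 1 (−0.10; −0.25 without control replicate 3), XRCC2 without knockdown replicate 1 (0.11), ALDOC without control replicate 2 (−0.11) and with median centring, and ATP5F1B with quantile normalisation (0.04). Their adjusted p ranged from 0.00164 to 0.149, 8.75e-05 to 0.119, 0.00182 to 0.07, 2.76e-05 to 0.0643 and 0.000391 to 0.359. The replicate block ended the INA6 calls of SEC61A1, HYOU1 and OGT. Calls were gained in INA6 by C1R without control replicate 3 (−0.21), SOCS1 with median centring and without control replicate 1 (0.19) or knockdown replicate 1 (0.19), and CIITA with median centring, and in JJN3 by EGR1 without control replicate 1 (0.21) and by CDC20 and JCHAIN with quantile normalisation. Depth is unknown, and the DESeq2 alternative was not run because the values are not counts.

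Every other split of 3 against 3 exchanges 1 library between the arms, so part of the arm difference stays in it. In each line 1 of the 10 splits, the real one, called as many genes (6084 and 6264), the others calling 0 with limma and up to 317 and 161 at an unadjusted p below 0.05. Likewise 1 of 10 called as many lists, 15 and 14, with 14 and 11 the highest of the others. With 10 splits the share cannot go below 0.1.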

Other observations

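The gene families below and all tests on them were chosen after the data were seen. Their adjusted p-values were adjusted over these 5 families only, which does not cover the choice of families. Subunits of the CCT chaperonin, which folds actin and tubulin, rose in both lines, 8 of 8 in each (median 0.37 in INA6, list adjusted p = 3.53e-06, and 0.29 in JJN3, 3.88e-05). With an estimated correlation these were adjusted p = 0.0944 and adjusted p = 0.0431. Core spliceosome and SR protein genes rose as well, 21 up and 0 down of 32 in INA6 (median 0.21, adjusted p = 3.53e-06) and 21 up and 1 down of 31 in JJN3 (0.15, 1.75e-05), with adjusted p = 0.062 and adjusted p = 0.0431 with an estimated correlation. Host transcripts of small nucleolar RNAs (SNHG) had 13 up and 2 down of 21 in INA6 (median 0.27, 7.68e-06) and 12 up and 3 down of 21 in JJN3 (0.14, 0.00456), with adjusted p = 0.062 and adjusted p = 0.104 with an estimated correlation. Genes with TMEM symbols fell, 59 down and 21 up of 163 in INA6 (median −0.08, 0.00377) and 63 down and 27 up of 162 in JJN3 (−0.06, 0.00896), with adjusted p = 0.121 and adjusted p = 0.069 with an estimated correlation. With libraries centred on their median the TMEM medians were −0.0456 and −0.0304. In INA6 4 and in JJN3 5 of the 5 families passed; 4 of the 10 splits called as many in INA6 (highest other 5) and 1 of 10 in JJN3 (highest other 4), too few splits for a share under 0.05.

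Zinc finger genes with ZNF symbols fell in JJN3, 164 down and 52 up of 429 (median −0.07, adjusted p = 0.0014; adjusted p = 0.069 with an estimated correlation). In INA6 113 were up and 63 down of 379 (median 0.05), which did not pass (adjusted p = 0.0597) but did with the expression trend removed (median 0.06, adjusted p = 0.00456, against 0.382 with an estimated correlation). With libraries centred on their median the ZNF medians were −0.0410 in JJN3 and 0.0841 in INA6. The difference between lines had an adjusted p = 5.59e-05 over 361 genes and an unadjusted p = 8.16e-06 with the expression trend removed. A p as small as the one with deposited values came from 20 of the 100 joint splits, the real one included (lowest other p 2.19e-07), and from 16 of the 81 that regroup both lines, so chance is not excluded for this difference.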
